A study of Rattus norvegicus with 6 samples.

How the data were processed

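Gene expression was measured in rat trophoblast stem cells, the self-renewing precursors of the placental trophoblast lineages, on 6 Affymetrix rat expression arrays. Per the labels, 3 arrays held cells kept in ambient oxygen (21%) and 3 held cells moved to 0.5% oxygen for 24 h. The treatment text attached to all 6 samples describes the exposure to 0.5% oxygen, including the 3 labelled ambient, so the groups were taken from each sample's treatment characteristic, which reads the same way as its title. Cultures were kept at 37 °C and 5% CO2 in RPMI-based medium with 20% serum, mixed as 30% fresh medium and 70% medium conditioned by rat embryonic fibroblasts. Total RNA was extracted with Trizol and 6 µg of it was turned into biotin-labelled cRNA. Nothing in the labels says that the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

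The deposited values are log2 probe set signals, 1 column per array, for 31099 probe sets. The submitters' processing notes name MAS5 and Affymetrix Expression Console without saying what each did, so the algorithm behind the values and any scaling target are not given in the sources used here. The lower and upper percentiles and the medians of the arrays lay close together (medians from 5.162 to 5.196 log2), which is how values already put on a common scale look. The mean of the linear signals between their 2nd and 98th percentiles ranged from 219.7 to 225.1, so it was not set to a fixed target. No detection calls were used, so a dim probe set could not be told from an absent transcript, and the number of arrays limits the precision.

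The log2 signals were returned to the linear scale, a pseudocount of 10.8 signal units (the 20th percentile of all signals) was added, and log2 was taken again. Log2 changes are on this scale, which understates the change of dim probe sets. The 57 Affymetrix control probe sets were set aside, and of the other 31042 the 18625 with a mean at or above the 40th percentile of all means (5.02 log2) were tested. Hypoxic minus ambient was fitted with limma (version 3.58.1 in R 4.3.3; lmFit, then eBayes with a trend of the variance on the mean) and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Adjusted p-values of single genes below all come from this limma fit. On simulated arrays with the means and spread of this comparison (18625 probe sets, 200 of them changed), the fit recovered 26% of changes of 0.25 log2 and 80% of those of 0.5. It recovered 100% of those of 1 and 2, and 3 of 156 calls were false. In the data 10266 probe sets were called. The Benjamini-Hochberg cutoff on p is looser when more change, so these shares do not describe recovery or false calls in the data.

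Gene names were taken from the platform annotation given for these probe sets. It gave 1 gene symbol to 20826 probe sets, several to 436 and none to 9780, and the last 2 kinds name no gene. Of the probe sets with 1 symbol, 20758 matched a rat gene in the RefSeq table of the GRCr8 assembly through the gene identifier, and 0 symbols needed an update. A gene with several probe sets (4525 of 14217 genes) was represented by the probe set of highest mean signal. Of the 2874 genes with at least 2 tested probe sets, 95 had both a higher and a lower probe set. Probe sets can also pick up transcripts of near-identical copies, as in the prolactin, Psg and Ceacam families, whose values are therefore uncertain.

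Gene lists, chosen before the data were examined from textbook knowledge of hypoxia, of rat trophoblast and of other cell types that such cultures could hold, numbered 23. They were HIF targets, glycolysis, oxidative phosphorylation, histone demethylases, matrix proteases, collagen modification, stem state, giant cells, junctional zone, labyrinth, cell cycle, DNA repair, ribosome biogenesis, stress responses, cholesterol, angiogenic factors, cytokines, autophagy, epithelial junctions, and fibroblast, endoderm, endothelial and blood markers. Each was set against all other tested genes with limma's camera (preset inter-gene correlation of 0.01, Benjamini-Hochberg over the 23 lists). Camera with an estimated correlation and fry were alternatives. Fry asks whether the members of a list move, not whether they move more than other genes. Estimating the correlation raised camera p-values even where the estimate stayed near the preset. For the HIF targets it was 0.011, and the unadjusted camera p went from 4.29e-22 to 0.000672. A pass lost in this way therefore does not by itself point to co-regulation of a list. The genes named were the 10 largest increases and 10 largest decreases among called genes with a full gene symbol whose groups did not overlap, up to 4 called members of each list with the largest absolute change (or, where fewer than 2 were called, the 2 largest tested), and Hif1a, Epas1, Arnt, Vegfa, Kdm3a, Mmp12, Cdx2, Eomes, Prl3d1, Tpbpa and Ascl2. Other members, named because they went against their list or made up a small count, were chosen after their values were seen.

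Alternatives were no pseudocount and a larger one, no filter and a stricter one, quantile normalization, centring on array medians, eBayes without the trend or robust, array weights, a block for the replicate number, each array left out in turn, and other probe sets of a named gene. Scaling on the poly-A spike-ins, scaling on the hybridisation spike-ins, and cyclic loess were added after seeing the data. Control probe sets were compared between groups with a two-sided exact permutation test, which cannot go below p = 0.1 for 3 against 3 arrays.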

Results

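The data comprised 6 arrays of rat trophoblast stem cells, 3 from ambient oxygen (21%) and 3 from cells exposed to 0.5% oxygen for 24 h. The comparison addresses how transcript levels in these cells respond to low oxygen. Genes tied to oxygen sensing and to trophoblast invasion were among those followed, but invasive behaviour itself was not measured. Arrays of the same group correlated at r = 0.9968 to 0.9982 over probe sets, and arrays of different groups at 0.9752 to 0.9776. The first principal component held 87.5% of the variance and separated the groups.

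On the arrays' common scale, a small set of genes changed strongly in 0.5% oxygen and a great many changed little. Both kinds of change went in both directions. Ankrd37, a classical HIF target, showed the largest increase, 21.7-fold (log2 change 4.44 ± 0.07, SE, n = 3 per group; adjusted p = 1.17e-12). It was followed by Plod2, a lysyl hydroxylase that modifies collagen (10.7-fold), the macrophage elastase Mmp12 (10.3-fold) and Ripor2 (8.29-fold). Over the alternatives Mmp12 reached a log2 change of 3.69 and Plod2 at most 3.58, so the order of these genes is not fixed. Zfp185 rose by 3.40 on the log2 scale, but its ambient signal of 4.78 lay below the filter value of 5.02, so that its fold and its rank depend on the pseudocount (4.07 without one; 2.95 to 4.07 over the alternatives). Bhlhe40, a transcriptional repressor, rose 6.76-fold, the liver-type glycogen phosphorylase Pygl 6.53-fold, the histone H3 lysine demethylase Kdm3a 6.48-fold, Guca1a 6.44-fold and the mitochondrial adenylate kinase Ak4 6.27-fold. The largest decrease was that of Myh1 (log2 change -2.46 ± 0.05), but its other 4 tested probe sets rose by 0.79 to 1.14, so that no direction can be given for this gene. The epithelial adhesion molecule Cdh1 (E-cadherin) fell by 2.13 ± 0.06 on the log2 scale, which is 4.37-fold. Further decreases were those of Gpatch4 (-1.87), the cold-inducible RNA-binding protein Rbm3 (-1.73), the S-adenosylmethionine synthetase Mat2a (-1.71), the nuclear receptor Nr2f2 (-1.61), the bHLH inhibitor Id1 (-1.53), Ooep (-1.52), Pm20d2 (-1.48) and Pak1ip1 (-1.43). The adjusted p of these 20 genes was at most 1.98e-07.

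Of 10507 genes tested, 6418 (61.1%) passed the threshold, 2592 higher and 3826 lower in 0.5% oxygen. At probe set level 10266 of 18625 passed, 4429 higher (43.1% of calls) and 5837 lower. Most changes were small: 5031 of the 6418 genes changed by less than 1.5-fold, while 203 genes rose and 111 fell by at least 2-fold. The 3 hypoxic arrays lay entirely above or below the 3 ambient arrays for 67.5% of tested genes, where chance gives 10%. All changes are relative to the arrays' common scale. Scaled on the poly-A spike-ins, RNAs added to each sample before labelling, the median change of tested probe sets moved from -0.015 to -0.459 and the calls became 555 higher and 11473 lower. Scaled on the hybridisation spike-ins the median was -0.201, with 1454 higher and 6627 lower. With arrays centred on their medians the split was 5163 to 5086. The balance of called genes changed by at least 2-fold turned round with spike-in scaling. It became 95 higher and 870 lower with poly-A and 144 higher and 269 lower with hybridisation spike-in scaling. Spike-in scaling subtracted the spike-in mean of each array, which itself varied within groups. For poly-A its SD was 0.12 in ambient and 0.22 in hypoxic arrays, and for hybridisation spike-ins 0.06 and 0.16. This spread was added to every gene, so a call can be lost through it as well as through a smaller change. Of the genes named below, Itga7, Pgf, Birc3, Mif, Cxcl14, Gabarapl1 and Cd68 stayed above 0 but no longer passed with poly-A scaling, and Amn, Pecam1, Eng, Lyz2, Arnt and Ascl2 stayed above 0 but no longer passed with hybridisation spike-in scaling. Another tested probe set gave a change in the same direction but smaller by over 1.5 times for Ripor2 (1.78), Gpatch4 (-1.06), Nr2f2 (-0.79), Vldlr (0.708), Pdk1 (1.48), P4ha2 (0.686), Loxl2 (0.621), Kdm2a (0.488), Stard4 (0.714), Rrp12 (-0.87), Prl8a2 (0.541), Fbln1 (0.829), Gabarapl1 (0.36), Cxcl14 (0.2) and Itga6 (-0.228 and -0.341), and a larger one for Col5a1 (0.383).

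Targets of the hypoxia-inducible factors (HIF) rose as a group. Of 43 tested members 38 were higher and 3 lower, with a median log2 change of 1.14 (0.70 after scaling on the poly-A spike-ins, with 28 higher and 4 lower, and 33 and 3 after hybridisation spike-in scaling); 23 members of this list also stood in other lists. The list exceeded other genes by camera (adjusted p = 9.87e-21) and also with an estimated correlation (adjusted p = 0.0155, the highest over the camera alternatives, of which the lowest was 1e-63). Besides Ankrd37, Plod2, Bhlhe40 and Kdm3a, the angiogenic factor Vegfa rose 3.42-fold (1.77 ± 0.05). The members that fell were the glucose transporter Slc2a3 (-1.40), the vasoactive peptide Adm (-0.84) and the carbonic anhydrase Car9 (-0.26), while Car12 (0.00068) and Stc2 (0.11) did not pass. The transcripts of the oxygen-regulated HIF subunits themselves were lower: Hif1a fell 2.28-fold (-1.19 ± 0.05, adjusted p = 1.19e-09) and Epas1, which encodes HIF-2 alpha, 2.16-fold (-1.11 ± 0.07, adjusted p = 3.16e-08). Their partner Arnt rose by 0.32 ± 0.09 (adjusted p = 0.00906), but changed by -0.12 after scaling on the poly-A spike-ins.

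**Figure D1:**
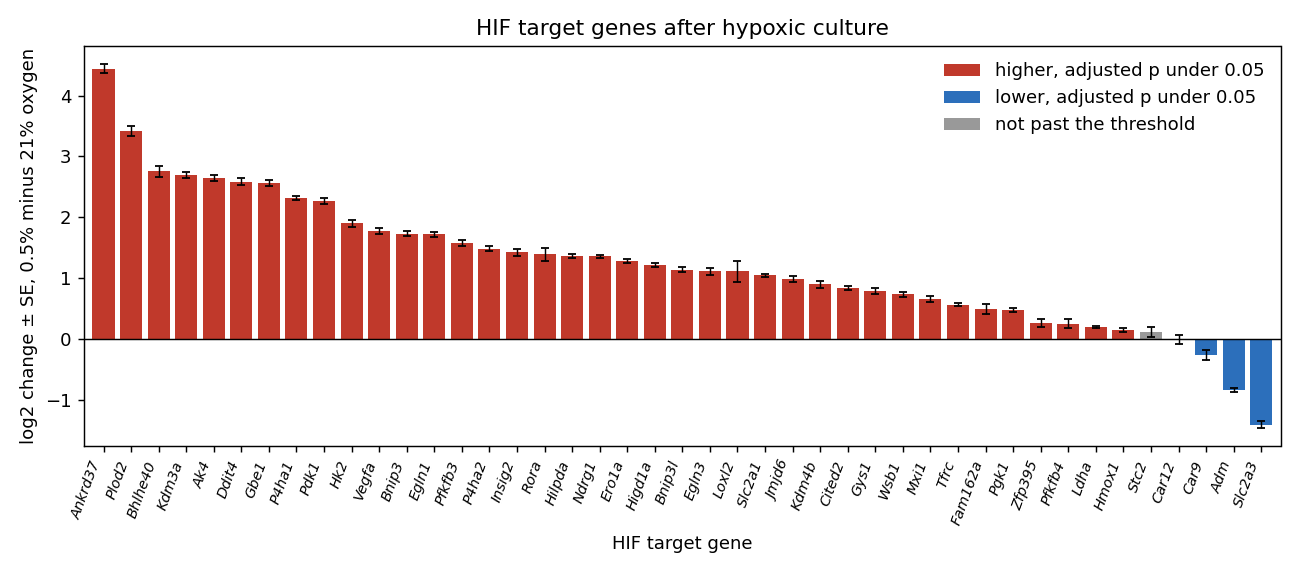
Log2 change (0.5% minus 21% oxygen, y axis) of each tested HIF target gene (x axis); bars are estimates from 3 arrays per group, error bars are SE, and colour marks the direction past adjusted p 0.05. Of 43 genes, 38 lie above 0 and past the threshold, led by Ankrd37 at 4.44.

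Genes of glucose uptake and glycolysis rose, 23 of 26 tested members, with a median change of 0.61 (0.17 after scaling on the poly-A spike-ins). The 23 higher and 1 lower became 11 and 3 after poly-A and 18 and 1 after hybridisation spike-in scaling. Of the 26 tested members 12 also stood in other lists. The list passed camera (adjusted p = 1.65e-13) but not with an estimated correlation (adjusted p = 0.07, the highest over the camera alternatives, of which the lowest was 1.4e-24). The glycogen branching enzyme Gbe1 rose 5.91-fold (2.56 ± 0.05), the enolase Eno2 5.67-fold, the aldolase Aldoc 5.54-fold and Pdk1, a kinase that inhibits pyruvate dehydrogenase, 4.81-fold. Slc2a3 was the member that fell, and Pfkm (0.0039) and Slc16a1 (0.0051) did not pass. Oxidative phosphorylation and the citrate cycle had 11 of 45 members higher and 18 lower (12 and 20 adjusted over the list alone; camera adjusted p = 0.346), but 0 and 34 after poly-A and 0 and 18 after hybridisation spike-in scaling. Its largest changes were decreases of the citrate cycle enzymes Idh3a (-0.72 ± 0.04), Ogdh (-0.65 ± 0.04), Dlst (-0.46 ± 0.03) and Mdh2 (-0.45 ± 0.03). Autophagy and mitochondrial turnover had 13 of 21 members higher and 6 lower, with a median of 0.15 that turned to -0.29 with poly-A (2 higher and 6 lower) and -0.03 with hybridisation spike-in scaling (3 and 6). Its camera adjusted p was 0.0241, and adjusted p = 0.171 with an estimated correlation, the highest over the camera alternatives, of which the lowest was 0.0175. The mitophagy receptors Bnip3 (3.33-fold) and Bnip3l (2.21-fold) and the ubiquitin-like Gabarapl1 (1.61-fold) rose, the cargo receptor Sqstm1 fell by 0.41 ± 0.03 (by 0.09 on another probe set), and Wipi1 (0.09) and Ulk1 (0.09) did not pass. Cholesterol synthesis and uptake had 9 of 20 members higher and 4 lower, with a median of 0.13 that turned to -0.32 with poly-A (3 higher and 7 lower) and -0.06 with hybridisation spike-in scaling (4 and 4). Camera gave adjusted p = 0.0274, and adjusted p = 0.379 with an estimated correlation, the highest over the camera alternatives, of which the lowest was 0.00796. Insig1, which retains the sterol sensor in the endoplasmic reticulum, rose 3.28-fold, squalene epoxidase Sqle 2.49-fold and the cholesterol carrier Stard4 2.23-fold, whereas Acat2 (-0.50 ± 0.06), Tm7sf2 (-0.32), Nsdhl (-0.24) and Idi1 (-0.21) fell.

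Ribosome biogenesis showed the lowest median of the 23 lists. Of 35 tested members 33 fell and 2 rose (Rrn3 by 0.43 and Ddx10 by 0.11), with a median of -0.66 that stayed below 0 under each scaling tried. The list passed camera (adjusted p = 1.13e-11) but not with an estimated correlation (adjusted p = 0.117, the highest over the camera alternatives, of which the lowest was 7.07e-16). The snoRNP protein Gar1 fell 2.56-fold (-1.36 ± 0.05), and the pre-rRNA processing factors Rrp12, Utp20 and Ftsj3 fell 2.48-fold, 2.33-fold and 2.29-fold. Cell cycle and DNA replication genes were likewise lower, 36 of 44 members, with 1 higher (Cdt1, 0.29) and a median of -0.32 that stayed below 0 under each scaling tried. Camera gave adjusted p = 1.1e-06, and adjusted p = 0.12 with an estimated correlation, the highest over the camera alternatives, of which the lowest was 1.65e-09. The cyclins Ccna2 (-0.98 ± 0.04) and Ccnb1 (-0.88 ± 0.04), the spindle checkpoint kinase Bub1 (-0.95 ± 0.04) and the anaphase activator Cdc20 (-0.94 ± 0.05) fell by a little under 2-fold. Another probe set of Cdc20 gave -0.25 and did not pass, while further probe sets of Cdc20 (-1.18) and Ccnb1 (-1.21) fell by more. In DNA repair 13 of 21 members fell and 2 rose (Msh6 by 0.45 and Bard1 by 0.24), but the list did not pass camera (adjusted p = 0.101), and 0 rose and 17 fell after poly-A or 0 and 13 after hybridisation spike-in scaling. The list did pass without the filter on dim probe sets (adjusted p = 0.0349, the lowest over the camera alternatives, of which the highest was 0.379). The recombination genes Rad51c (-1.05 ± 0.06) and Rad54l (-0.60 ± 0.07), the checkpoint kinase Chek1 (-0.73 ± 0.06) and the exonuclease Exo1 (-0.58 ± 0.04) were among those that fell.

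Histone lysine demethylases, oxygen-dependent enzymes in most families, had 13 of 20 members higher and 6 lower, with a median of 0.19 that was -0.25 after poly-A (5 higher and 6 lower) and 0.0062 after hybridisation spike-in scaling (8 and 6). The list passed camera (adjusted p = 0.0133) but not with an estimated correlation (adjusted p = 0.213, the highest over the camera alternatives, of which the lowest was 0.000407). Kdm3a, the largest increase at 2.70 ± 0.04, was well above Kdm6b (1.03 ± 0.09), Jmjd6 (0.99 ± 0.04) and Kdm2a (0.98 ± 0.06), and Kdm4d (0.07) did not pass. Jmjd6 is a lysyl hydroxylase that was counted in this list. The 3 members Kdm3a, Jmjd6 and Kdm4b also stood in the HIF list. Matrix proteases and their inhibitors had 14 of 24 members higher and 3 lower (Mmp15 -0.64, Adam19 -0.47 and Adam17 -0.28), with 11 more too dim to test. Their median of 0.18 turned to -0.27 with poly-A (4 higher and 9 lower) and -0.0069 with hybridisation spike-in scaling (8 and 3); camera gave adjusted p = 0.00159, and adjusted p = 0.117 with an estimated correlation, the highest over the camera alternatives, of which the lowest was 9.48e-05. Mmp12 rose from 5.64 ± 0.01 to 9.01 ± 0.03 log2 units (SD, n = 3), a change of 3.37 ± 0.06 (SE; adjusted p = 1.33e-12). The gelatinase Mmp9, already bright in ambient oxygen at 11.04 ± 0.04, rose 2.02-fold, Mmp17 1.87-fold and heparanase (Hpse) 1.79-fold. Heparanase was counted in this list but is not a protease. Collagen modification and matrix genes had 11 of 19 members higher and 1 lower (Lamc1, -0.51; 11 and 2 adjusted over the list alone), with a median of 0.17 that turned to -0.28 with poly-A (4 higher and 8 lower) and -0.02 with hybridisation spike-in scaling (8 and 2). Camera gave adjusted p = 0.000416, and adjusted p = 0.213 with an estimated correlation, the highest over the camera alternatives, of which the lowest was 3.78e-08. The members that rose most were enzymes that modify collagen, Plod2, the prolyl hydroxylases P4ha1 (4.97-fold) and P4ha2 (2.80-fold) and the lysyl oxidase Loxl2 (2.16-fold). Each of these also stood in the HIF list, and 8 of the 19 tested members stood in other lists. The change of Loxl2 (1.11 ± 0.17) rests in part on ambient replicate 3, which read 8.44 against 9.27 and 9.26 on ambient replicates 1 and 2.

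**Figure D2:**
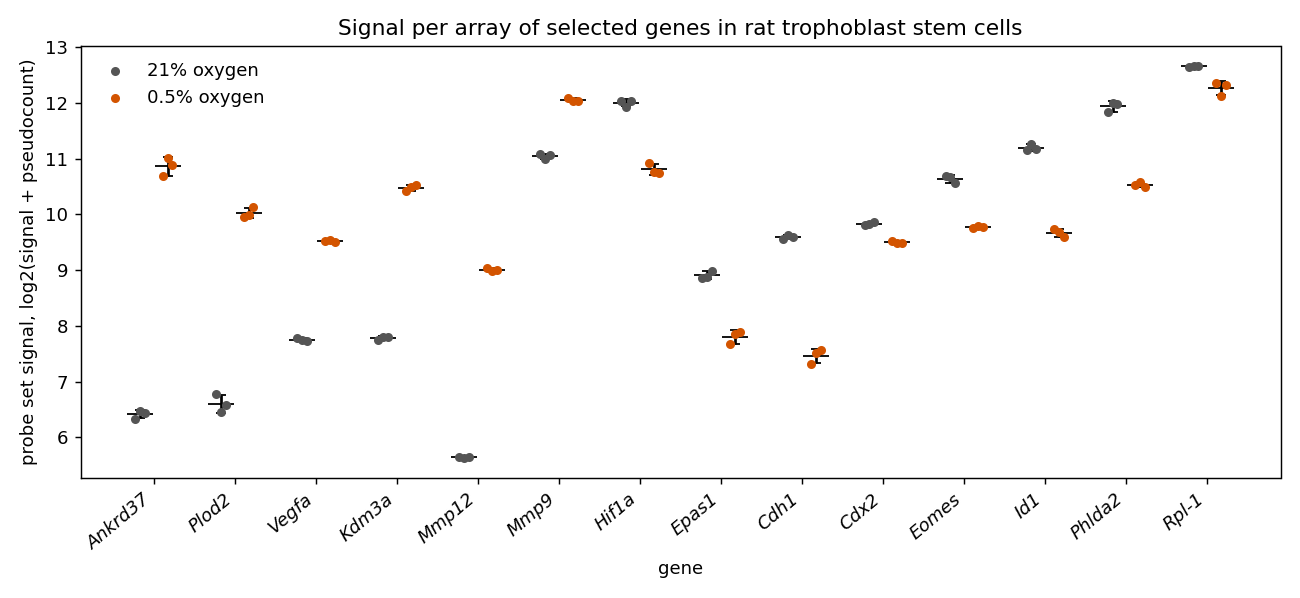
Signal per array (y axis, log2 of signal plus pseudocount) of 14 genes (x axis) in 21% and 0.5% oxygen; points are arrays, horizontal ticks are means and error bars are SD (n = 3). The groups do not overlap for any gene shown, and Mmp12 moves from 5.64 to 9.01 while Hif1a moves down to 10.81.

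Of genes of the trophoblast stem state 14 of 26 tested members were lower and 7 higher (15 and 8 adjusted over the list alone; camera adjusted p = 0.346). After poly-A spike-in scaling 16 were lower and 2 higher, and after hybridisation spike-in scaling 15 and 3. Eomes, a T-box factor needed for trophoblast stem cells, fell 1.82-fold (-0.86 ± 0.04, adjusted p = 5.08e-09), and Cdx2, a caudal homeobox factor of the trophectoderm, fell by 0.32 ± 0.04 (adjusted p = 1.12e-05). Id1 and Bmp4 (-1.28 ± 0.06) fell, whereas Id3 (1.63 ± 0.07) and Cdcp1 (1.51 ± 0.05) rose. Sox2 (0.12), Dusp6 (0.16), Spry4 (0.12), Fgfr2 (0.02) and Ly6e (-0.13) did not pass. Genes of trophoblast giant cells had 12 of 20 members lower and 5 higher (13 and 5 adjusted over the list alone; camera adjusted p = 0.268), and 15 lower and 1 higher after poly-A or 13 and 1 after hybridisation spike-in scaling. The steroid side-chain cleavage enzyme Cyp11a1 fell by 1.18 ± 0.08, the giant cell factor Hand1 by 0.78 ± 0.06 and cyclin E1 (Ccne1) by 0.53 ± 0.04. The probe set named Rpl-1, listed as the placental lactogen gene with the synonym Prl3d1, fell by 0.40 ± 0.05 (adjusted p = 1.69e-05), from a bright 12.66 ± 0.01 in ambient oxygen. The matched members that rose were Prl8a2 (1.14 ± 0.10), Lifr (0.38), Podxl (0.26), Prl8a9 (0.25) and Ada (0.14), and Prl7a3 (-0.14), Flt1 (-0.06) and Prl2a1 (0.05) did not pass. This list also held the name Stra13, which was not matched to Bhlhe40. Bhlhe40 rose by 2.76 and was counted in the HIF list alone, so the giant cell counts leave it out.

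Genes of the junctional zone and invasive trophoblast had 7 of 17 members higher and 7 lower (camera adjusted p = 0.462), but 2 and 9 after poly-A and 5 and 7 after hybridisation spike-in scaling. Mmp12 and the HIF co-regulator Cited2 (0.84 ± 0.03) rose, while the imprinted growth restrictor Phlda2 fell 2.65-fold (-1.41 ± 0.04) and the steroidogenic enzyme Cyp17a1 fell by 1.00 ± 0.06. Krt7 (0.01), Flt1 (-0.06) and Nostrin (0.15) did not pass. Ascl2, a bHLH factor of junctional zone precursors, rose by 0.42 ± 0.13 (adjusted p = 0.0124), but by 0.28 without hypoxic replicate 3 (adjusted p = 0.0554) and changed by -0.02 after poly-A spike-in scaling (adjusted p = 0.916), with adjusted p from 0.000929 to 0.916 over the alternatives. Tpbpa, the spongiotrophoblast marker, was too dim to test (4.85 ± 0.05 in ambient and 4.96 ± 0.05 in hypoxic arrays). Syncytiotrophoblast and labyrinth genes had 6 of 18 members higher and 4 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.268), and 2 and 12 after poly-A or 4 and 6 after hybridisation spike-in scaling. The lactate exporter Slc16a3 and the glucose transporter Slc2a1, both also in other lists, rose 2.10-fold and 2.07-fold and the integrin Itga7 1.52-fold, while Cebpa (-0.75 ± 0.07), Dlx3 (-0.53), Lgals3 (-0.39) and Tfeb (-0.15) fell. Of epithelial junction and mesenchymal transition genes 9 of 24 were higher and 6 lower (camera adjusted p = 0.393), and their median (0.06) and mean (-0.09) differed in sign. After poly-A spike-in scaling 0 were higher and 14 lower, and after hybridisation spike-in scaling 0 and 6. After Cdh1, whose signal went from 9.59 ± 0.04 to 7.46 ± 0.13 log2 units (SD, n = 3), the integrins Itga6 (-0.65 ± 0.05) and Itgb4 (-0.60 ± 0.08) and the claudin Cldn4 (-0.57 ± 0.06) fell most.

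**Figure D3:**
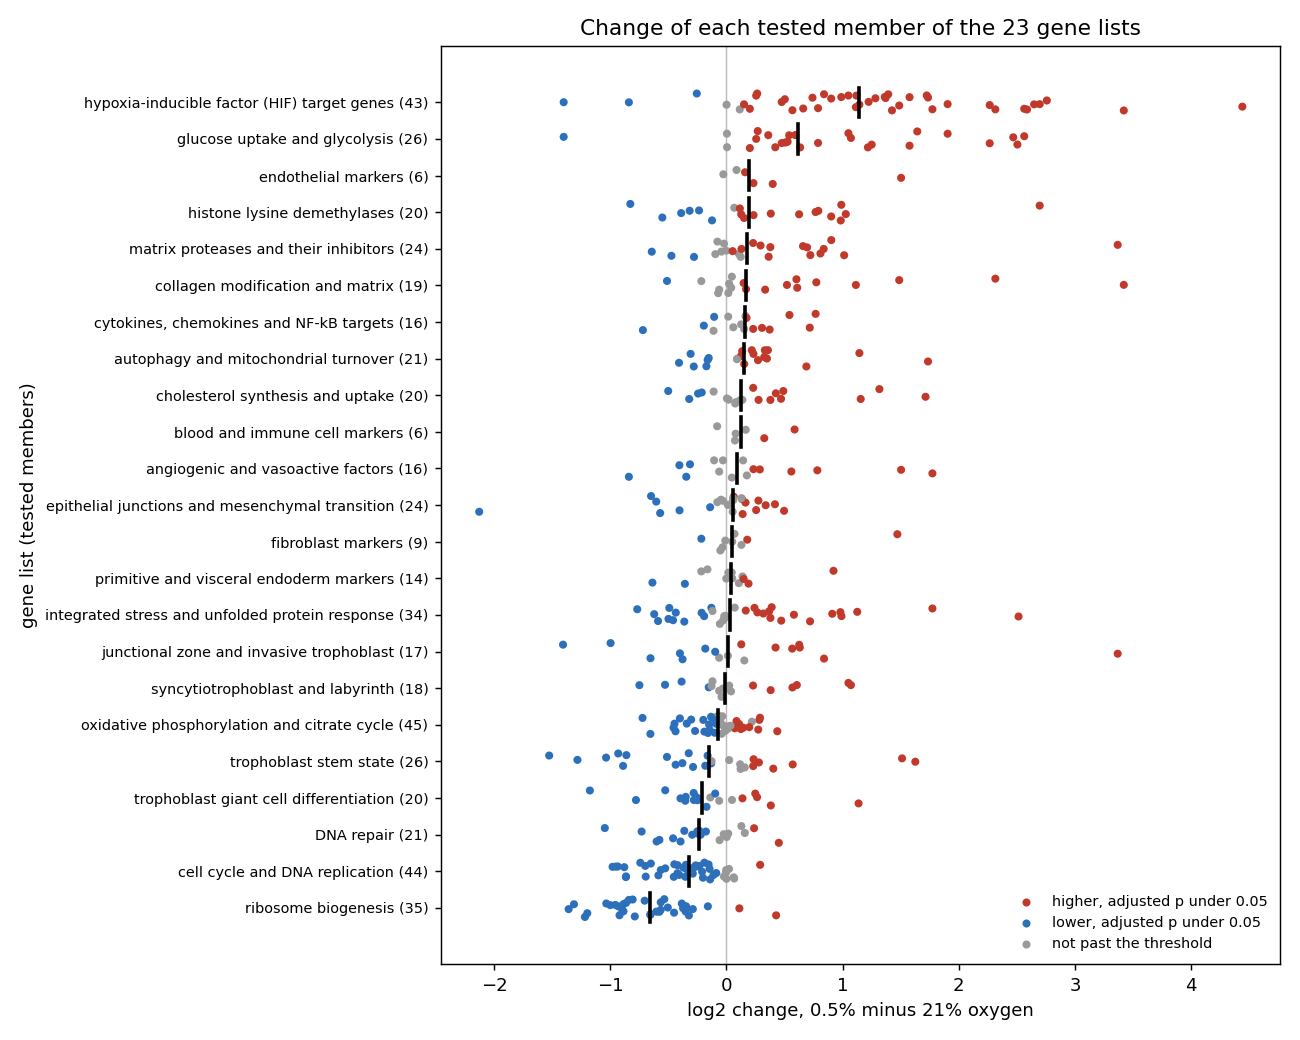
Log2 change (0.5% minus 21% oxygen, x axis) of each tested member of the 23 lists (y axis, number of tested members in brackets); points are genes, colour marks the direction past adjusted p 0.05 and black ticks are medians. HIF targets have the highest median (1.14) and ribosome biogenesis the lowest (-0.66).

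The integrated stress and unfolded protein response list had 16 of 34 members higher and 11 lower (16 and 12 adjusted over the list alone; camera adjusted p = 0.0974). Camera put the list past the threshold, as higher relative to the other genes, after spike-in scaling. With poly-A this gave adjusted p = 0.0111 (6 higher and 17 lower), with hybridisation adjusted p = 0.0141 (8 and 12). Scaling shifts all genes of an array alike and so cannot move the list relative to other genes. These passes are therefore no added evidence. Over the camera alternatives adjusted p ran from 0.0111 to 0.213. The lipoprotein receptor Vldlr rose 5.71-fold, Vegfa, which also stands in the HIF list, 3.42-fold, the endoplasmic reticulum co-chaperone Dnajb9 2.18-fold and the stress factor Ddit3 1.99-fold. Among the members that fell were the transcription factor Atf4 (-0.77) and the serine synthesis enzymes Psat1 (-0.62) and Phgdh (-0.59). Angiogenic and vasoactive factors had 6 of 16 members higher and 4 lower (7 and 4 adjusted over the list alone; camera adjusted p = 0.205), and 2 and 8 after poly-A or 4 and 4 after hybridisation spike-in scaling. Beside Vegfa, its receptor Kdr rose 2.83-fold and placental growth factor Pgf 1.72-fold, while Adm, Ccn1 (-0.41), Vegfb (-0.35) and Hbegf (-0.31) fell. Of cytokines, chemokines and NF-kB targets 7 of 16 were higher and 3 lower, with 14 too dim to test (camera adjusted p = 0.101), and 0 higher and 5 lower after poly-A or 3 and 3 after hybridisation spike-in scaling. Birc3 (0.77 ± 0.08), Mif (0.72 ± 0.03) and Cxcl14 (0.54 ± 0.08) rose, and Bcl3 (-0.72 ± 0.06; -0.25 and not past the threshold on another probe set), Nfkbia (-0.19) and Sod2 (-0.11) fell. For the lists above with no such value, the counts adjusted over the list alone were the same as those over all probe sets.

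Among markers of other cell types, those of fibroblasts and of blood and immune cells were mostly dim. Of the blood and immune markers on the array 13 of 19 were too dim to test. For endothelial markers this was 6 of 12, and for endoderm markers 6 of 20. Of the fibroblast markers 13 of 22 were too dim to test, Fbln1 (1.47 ± 0.06) and Col5a1 (0.18 ± 0.07) were higher and Acta2 (-0.22 ± 0.07) lower; adjusted over the list alone 1 was higher and 0 lower, and after poly-A spike-in scaling 1 was higher and 5 lower (1 and 1 after hybridisation spike-in scaling). Col5a1 lost its call with the replicate block, without the filter and without ambient replicates 1 or 2 or hypoxic replicates 2 or 3 (0.129 to 0.202; adjusted p over the alternatives from 0.00257 to 0.971), and Acta2 without the filter, with arrays centred on their medians and without ambient replicates 1 or 2 or hypoxic replicate 2 (-0.216 to -0.173; 0.00115 to 0.0995). Of 14 primitive and visceral endoderm markers Thbd (0.92 ± 0.08), Amn (0.19 ± 0.07) and Lamb1 (0.15) were higher and Sox7 (-0.64 ± 0.09) and Foxa2 (-0.36 ± 0.11) lower. These 3 and 2 became 1 higher and 9 lower after poly-A and 1 and 4 after hybridisation spike-in scaling. Amn lost its call with the replicate block, without the filter and without ambient replicates 1, 2 or 3 or hypoxic replicates 1 or 2 (0.169 to 0.197; adjusted p over the alternatives from 0.0076 to 0.986), and Foxa2 without ambient replicate 2 or hypoxic replicates 2 or 3 (-0.327 to -0.253; 7.22e-05 to 0.0841). Kdr, Pecam1 (0.40 ± 0.08), Eng (0.23 ± 0.08) and Esam (0.16 ± 0.05) of the 6 tested endothelial markers were higher, and Sox18 (-0.03) and Egfl7 (0.09) did not pass. Eng lost its call without the filter and without ambient replicates 2 or 3 or hypoxic replicates 1 or 2 (0.164 to 0.233; adjusted p from 0.0114 to 0.81 over the alternatives). The endothelial list passed camera without hypoxic replicate 3 (adjusted p = 0.0321), but not in the main comparison (0.0679, with 0.0321 to 0.379 over the camera alternatives). It also passed after poly-A (0.0376, with 1 higher and 1 lower) and hybridisation spike-in scaling (0.0451, with 1 and 0). The passes after scaling are no added evidence, since scaling shifts all genes of an array alike. Of the 6 tested blood and immune markers Cd68 (0.59 ± 0.08) and Lyz2 (0.33 ± 0.09; 0.237 with adjusted p = 0.0534 without hypoxic replicate 2, and 0.0018 to 0.553 over the alternatives) were higher, while Csf1r (0.17), C1qa (0.08), Cd14 (-0.08) and Hbb (0.07) did not pass. After poly-A spike-in scaling 0 were higher and 1 lower, and after hybridisation spike-in scaling 1 and 0. The ambient means of Thbd, Lyz2 and Cxcl14 also lay below the filter value, so the sizes of their changes depend on the pseudocount. Camera did not pass for the fibroblast (adjusted p = 0.294), endoderm (0.393) or blood and immune lists (0.226), and after scaling on the poly-A spike-ins Col5a1, Amn, Pecam1, Eng, Esam and Lyz2 were below 0.

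The array controls bear on RNA quality and scaling. The signal of the 3' probe set minus that of the 5' probe set of beta-actin was 1.36 ± 0.09 log2 units in ambient and 1.44 ± 0.07 in hypoxic arrays (SD, n = 3; exact permutation p = 0.2). For Gapdh these values were 0.21 ± 0.02 and 0.20 ± 0.01 (exact p = 0.8). The 5' probe set of hexokinase was too dim (3.59 and 3.68 log2 units) for this comparison. The 18 hybridisation spike-in probe sets averaged 11.08 ± 0.06 in ambient and 11.26 ± 0.16 in hypoxic arrays (exact p = 0.3), with 15 of the 18 higher in hypoxic arrays. With 3 arrays per group these tests cannot reach a p under 0.1.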

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

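In this part the tests on spike-ins, with cyclic loess and on other splits were chosen after the values were seen, while camera with an estimated correlation was set beforehand. The poly-A spike-ins, bacterial RNAs added to a sample before labelling, were outside the comparisons above and differed between the groups. Their 24 probe sets averaged 7.75 ± 0.12 log2 units in ambient and 8.19 ± 0.22 in hypoxic arrays (SD, n = 3), a difference of 0.444 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Each of the 24 probe sets was higher in the hypoxic group, and the 3 hypoxic arrays (8.40, 7.95 and 8.22) lay above the 3 ambient arrays (7.77, 7.61 and 7.86). No explanation of those tested was argued against by these values. Brighter hybridisation of the hypoxic arrays would raise the hybridisation spike-ins by as much. The poly-A minus hybridisation difference between groups was 0.258 with an SE of 0.177, and single arrays overlapped, so this stays open. The hybridisation mean also pools unlike probe sets. Those of bioB and bioC differed by 0.258 to 0.327, of bioD by 0.0985 to 0.212 and of cre by -0.0482 to 0.0148. More spike-in per unit of RNA in the hypoxic samples would move the 4 spike-in transcripts alike, and their differences spanned 0.0938 (0.394 to 0.488). Less cellular mRNA per unit of total RNA in 0.5% oxygen, the biological candidate, predicts the same values with a mean difference above 0, such as the 0.444 seen. The last 2 explanations cannot be told apart, because each spike-in addition went with a sample of a single group.

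The fall of ribosome biogenesis genes (median -0.66, SE 0.0813 for the median) was set against technical explanations as well. The SE of a list median is taken over member genes on the same arrays, as if they were independent. It does not measure uncertainty between samples. A trend of the change with signal level would vanish after cyclic loess. The median of the list was -0.588 there (SE over genes 0.0801), against -0.66 without it. A single wrong scaling factor for whole arrays would lower the hybridisation spike-ins by as much, yet these differed by 0.186 (SE 0.0995) in the other direction. Both results argue against these explanations as the whole cause, though the spike-ins do not track the amount of RNA put on an array. A response to 0.5% oxygen remains a hypothesis, since it was found on these arrays. Co-regulation of the members was not settled by camera with an estimated correlation (0.113 for this list). The list did not pass there (adjusted p = 0.117, in a range from 7.07e-16 to 0.117 over the camera alternatives). That setting also raises p where the estimate is near the preset, so co-regulation stays open.

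The 6 arrays can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 10266 probe sets and 6418 genes by limma, where the highest of the other splits gave 0 and 0 (at an unadjusted p under 0.05, 10984 and 6815 in the real split and at most 345 and 119 in the others); in each case 1 of the 10 splits reached the real value. For lists past the camera threshold the real split gave 9 and the highest other 8, so again 1 of the 10 splits reached the real value. Each of the other splits sets 2 arrays of one group and 1 of the other against the rest, so a part of the real difference stays in it and the remainder widens its spread. The few limma calls and the lists passing there follow from this and say nothing about chance.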

How the results depend on the processing

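Spike-in scaling and cyclic loess were chosen after seeing the data. Of 93 counts and shares over the alternatives, 81 stayed within their limits (1.5 times the main value for counts, its 95% binomial interval for the share of higher calls, 1 within-group SD for spike-in differences); of 483 list values 456 and of 2012 named-gene values 1954 kept direction and side of the threshold. Probe sets called ranged from 8081 (hybridisation spike-in scaling) to 12028 (poly-A scaling), against 10266. The share of higher calls (43.14%) was 44.19% without the filter, 41.93% with the stricter one, 45.59% after quantile normalization, 50.38% with median centring, 50.54% after cyclic loess, 17.99% with hybridisation and 4.614% with poly-A spike-in scaling, and 41.97% to 43.45% with single arrays left out. Median centring and both spike-in scalings shift all probe sets of an array alike. Otherwise the cause was not tested. Lists past the camera threshold (9) became 11 with poly-A and 11 with hybridisation spike-in scaling. Those added by scaling are no further evidence, since such a shift cannot move a list relative to other genes. The count was 10 without the filter, 10 without hypoxic replicate 3 and 1 with an estimated correlation. It was 22 with directional fry and 23 with mixed fry, which ask other questions. Fry put the epithelial list lower while its median was 0.0551 (fry adjusted p = 0.0376; camera alternatives from 0.334 to 0.576). With poly-A scaling Col5a1 (-0.265), Amn (-0.254), Pecam1 (-0.046), Eng (-0.212), Esam (-0.284), Lyz2 (-0.119), Arnt (-0.123) and Ascl2 (-0.0219) reversed, and with hybridisation scaling Col5a1 (-0.00738) and Esam (-0.0265). Other probe sets of Bcl3 (-0.251) and Cdc20 (-0.248) did not pass, 1 of Amn gave -0.019, and those of Myh1 gave 1.14, 1.14, 1.07 and 0.791; the cause was not tested. The replicate numbers did not pair the samples: deviations from the group means of same-numbered arrays correlated at -0.0546, 0.042 and -0.114 over probe sets, and not every sample correlated best with its own number. With a replicate block 9928 probe sets and 6242 genes were called, 42.79% of the probe sets higher, and 9 lists passed. The filter left 12417 of the 31042 probe sets untested. That count was fixed in advance by placing the filter at the 40th percentile, so it does not measure how much signal was low.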

Other observations

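The gene groups in this part were chosen after the changes of single genes had been seen, so their tests describe these arrays and are no independent evidence. Some tested members already stood in the 23 lists above. They were 4 of 15 for glycogen metabolism, 3 of 19 for FOXO factors and targets and 6 of 18 for serine and folate metabolism. For NRF2 targets this was 1 of 18 and for mitochondrial protein import 0 of 24. Genes of glycogen metabolism were prominent among the increases. Of 15 tested members 8 rose, led by Pygl (2.71 ± 0.03, SE), Gbe1 (2.56 ± 0.05), the glycogen-binding protein Stbd1 (2.22 ± 0.08), the phosphoglucomutase Pgm1 (1.64 ± 0.04) and glycogenin Gyg1 (1.08 ± 0.07), so that enzymes of synthesis and of breakdown rose side by side. The phosphorylase kinase subunits Phkb (-0.96 ± 0.09) and Phkg2 (-0.17 ± 0.06) and the brain-type phosphorylase Pygb (-0.36 ± 0.03) fell (camera adjusted p = 0.000834 over 5 such lists, and adjusted p = 0.101 with an estimated correlation). FOXO factors and their targets had 15 of 19 members higher and 3 lower, with Foxo3 at 2.10 ± 0.07, the cyclin G2 gene Ccng2 at 1.90 ± 0.09, Foxo4 at 1.58 ± 0.07, Bcl6 2.83-fold higher and the cell cycle inhibitor Cdkn1b at 1.21 ± 0.05 (camera adjusted p = 3.99e-05, and adjusted p = 0.107 with an estimated correlation). The members that fell were Cat (-0.47), Irs2 (-0.24) and Sod2 (-0.11). The groups in this part were not refitted with spike-in scaling. Scaling on the poly-A spike-ins lowers log2 changes by their group difference of 0.444. The glycogen (0.446) and FOXO (0.401) medians are of that size, so their rise depends on the arrays' common scale.

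Serine and folate one-carbon metabolism went the other way, with 13 of 18 members lower, among them Mat2a (-1.71 ± 0.09), Mthfd1 (-1.11 ± 0.05), Shmt1 (-0.94 ± 0.05) and the purine synthesis enzymes Atic (-0.81 ± 0.03) and Pfas (-0.76 ± 0.05). Mat2b, the regulatory partner of Mat2a, rose by 1.06 ± 0.04 and Mthfd1l by 0.70 ± 0.06 (camera adjusted p = 0.00103, and adjusted p = 0.101 with an estimated correlation). Mitochondrial protein import had 18 of 24 members lower, led by the small chaperones Timm10 (-1.28 ± 0.05) and Timm9 (-0.99 ± 0.05), while Tomm7 (0.87 ± 0.03) and Timm17b (0.26 ± 0.06) rose (camera adjusted p = 0.000239, and adjusted p = 0.101 with an estimated correlation). Antioxidant NRF2 targets gave a negative result as a list, with 6 of 18 higher, 9 lower and a median of -0.01 (camera adjusted p = 0.52). Its larger changes were nevertheless decreases, of Srxn1 (-1.19 ± 0.06), Nqo1 (-1.16 ± 0.03), Gpx2 (-1.14 ± 0.08), Gclm (-0.86 ± 0.05) and Gclc (-0.65 ± 0.06).

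Some genes of similar function, picked as examples after their values were seen, moved apart. Id1 fell by 1.53 ± 0.04 while Id3 rose by 1.63 ± 0.07, and the glucose transporter Slc2a1 rose by 1.05 ± 0.03 while Slc2a3 fell by 1.40 ± 0.06. Adm fell by 0.84 ± 0.03 from a bright 12.36 ± 0.01 log2 units (SD, n = 3) in ambient oxygen, although it stands among the HIF targets of which 38 of 43 rose. The differences between the genes of each pair were not tested against each other.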
